A study of Homo sapiens with 8 samples.

How the data were processed

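RNA from A375-LM3 cells, a derivative of the established human melanoma cell line A375, was hybridised to Illumina HumanHT-12 V4 BeadChips, 1-colour arrays on which each probe gives 1 intensity. The 8 arrays fall into 4 groups of 2 by their labels: cultured cells carrying an empty vector, cultured cells expressing JMJD3, and cells of each kind that had been taken from a primary tumor, dissociated and kept in culture for 3 passages. The labels give 1 day of culture for the cultured cells, so dissociation and length of culture differ between the origins together with growth in a tumor. The labels number the 2 arrays of each group but do not say whether they came from separate cultures or tumors, so p-values measure the spread between these arrays, which may be technical in part.

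Per the labels' protocols, total RNA was extracted with a phenol-based reagent and amplified and labelled with biotin using the Illumina TotalPrep kit. Per the series' design text, the arrays were scanned on an Illumina HiScan and analysed in GenomeStudio, framework version 2011.1 with Gene Expression module 1.9.0. The deposited intensity values form 1 table of 47323 probes on a linear scale. The normalization method is not given in the sources used here. From the values, the sorted columns of the 8 arrays differed by at most 0.0057 on the log2 scale, which is what quantile normalization leaves, and the lowest intensity was 110.7, so no background had been subtracted. The median intensity was 152.6 and the highest 31938. A table from before normalization was not used in any step, because its 8 signal columns and their detection p-values, 16 columns in all, carry names that match no sample label.

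Because the detection p-values were not used, 3 steps departed from the design set before the data were examined. Dim probes were filtered on intensity instead of detection p. The background level was estimated from all values as the mode of the log2 intensities, 139.7, with the spread of the values below it mirrored, SD 0.0892. A probe counted as above background on an array when it exceeded 161.4, the one-sided 0.01 point of that distribution. The background was corrected with normexp on the deposited values with an offset of 16, in place of a fit to raw signals, and no further normalization was applied. The normexp fit gave a mean background of 118.3. This rule for the background level was chosen after the values had been seen, and a first version based on 1 array is among the alternatives. Slide positions are not given in the sources used here, so no slide block was fitted, and scaling to equal medians was not run because the columns already share 1 distribution.

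Probes were named from the platform annotation. Of the probes, 30113 had 1 gene symbol, 8 had several and were not named, and 17202 were not listed with a gene. Entrez identifiers matched 30074 probes to the RefSeq gene table of GRCh38.p14, and no symbol changed. The genome build of the array annotation is not given in the sources used here, so no coordinates are reported. A total of 22287 probes exceeded the background level on at least 2 of the 8 arrays, and they named 12415 genes. Each gene was represented by its probe with the highest mean. Other probes of a named gene are mentioned where they differed in direction.

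Differences were tested on the log2 scale with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with 1 model of 4 group means over all 8 arrays, 4 residual degrees of freedom and 5.11 prior degrees of freedom. The 5 contrasts were JMJD3 against vector in cultured cells, the same in tumor-dissociated cells, tumor-dissociated against cultured cells for each of vector and JMJD3, and the difference of the JMJD3 effect between the 2 origins. Genes with a Benjamini-Hochberg adjusted p under 0.05 within a contrast were called. Adjusted p-values without another source are limma's. With 2 arrays against 2, an exact permutation test cannot give a p below 0.333, so every p rests on limma's pooled estimate of the spread. By chance 33.3% of genes separate 2 arrays from 2 without overlap. Where a gene was not above background on either array of the dimmer group, the ratio is a bound and is given as "at least N-fold": the dimmer group's values were first raised to the lowest corrected value above background on the same array.

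A total of 23 gene lists with 508 genes were fixed before the data were examined, and 420 of their entries were tested. They cover NF-kB targets, BMP and SMAD signalling, secreted angiogenic and growth factors, Polycomb and H3K27 enzymes, HOX genes, melanocyte differentiation, an invasive melanoma state, epithelial-mesenchymal transition, extracellular matrix, interferon-stimulated genes, antigen presentation, cell cycle, p53 targets, hypoxia, the unfolded protein response, cholesterol synthesis, MAPK output, heat shock and immediate early genes, ribosomal proteins, and markers of fibroblasts, leukocytes, endothelium, and keratinocytes or erythroid cells. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 23 lists of a contrast, and again with an estimated correlation. All 40 list calls made with the preset correlation were lost with an estimated one, whose adjusted p is given beside each list described. Correlation among members was not the only reason. For fibroblast markers it was estimated at -0.0015, below the preset 0.01. Even so, camera's unadjusted p for tumor-dissociated against cultured vector cells went from 8.02e-10 to 0.00303. The loss of a call is therefore not evidence that the members of a list were correlated. Overlaps of called genes are given with the count for independent lists. Because 1 residual spread per gene enters all contrasts of the 8-array fit, the one-sided Fisher's exact test is given for calls from fits of only the compared groups, which share neither arrays nor a spread. This took the place of the planned test on the 8-array fit and was chosen after the overlaps had been seen.

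Genes were named by a rule fixed before the data were examined: the JMJD3 gene KDM6B first, then per contrast the 8 largest rises and the 8 largest falls among called genes whose 2 groups did not overlap, then up to 4 members with the smallest p from each list described, and CCL2, STC1, BMP4 and CXCL8 in both JMJD3 contrasts whatever their values. Names outside this rule were chosen after their values were seen and are said to be so.

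The fit was tested on simulated data with 12415 genes, each with its mean over the 8 arrays. Each gene had limma's pooled spread, the same in all 4 groups, so the wider spread of tumor-dissociated arrays was not simulated. A log2 change of 1 was called in 79% of changed genes for JMJD3 against vector in cultured cells, 77% for the same in tumor-dissociated cells, 74% and 83% for tumor-dissociated against cultured vector and JMJD3 cells, and 23% for the difference of the JMJD3 effect. A log2 change of 2 was called in at least 98% in each. With 100 genes changed at each size, unchanged genes falsely called numbered 15, 7, 10, 20 and 16, in the order above. For arrays the number of arrays limits the precision.

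Alternatives covered the background correction, the offset, cyclic loess on top, the filter on dim probes, all probes in place of 1 per gene, array weights, a fit of only the compared groups, a 2-fold minimum, a stricter adjusted p of 0.01, the replicate number as a block, and leaving out each array in turn.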

Results

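The study asked which genes respond to JMJD3, the histone H3K27 demethylase encoded by KDM6B, in A375-LM3 melanoma cells. Expression was measured on 8 arrays, 2 for each of cultured vector cells, cultured JMJD3 cells, tumor-dissociated vector cells and tumor-dissociated JMJD3 cells. Each array had between 19913 and 19923 probes above the background level. These counts are near equal by construction, because the arrays share 1 intensity distribution and 1 background level. The 2 arrays of a group correlated across genes with r of 0.993 in cultured vector cells, 0.990 in cultured JMJD3 cells, 0.982 in tumor-dissociated vector cells and 0.981 in tumor-dissociated JMJD3 cells. The residual spread was accordingly wider in tumor-dissociated cells, with an SD of 0.198 for vector and 0.206 for JMJD3 on the log2 scale, against 0.130 and 0.147 in culture. The first principal component held 54.0% of the variance and separated the 4 cultured from the 4 tumor-dissociated arrays. Replicate 2 of the tumor-dissociated vector cells and replicate 1 of the tumor-dissociated JMJD3 cells lay farthest apart on the second component, which held 19.6%.

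KDM6B itself was measured by 1 probe, close to background on every array. Its mean intensity was 147.4 ± 4.11 (SD, n = 2) in cultured vector cells, 152.9 ± 4.14 (n = 2) in cultured JMJD3 cells, 144.5 ± 5.52 (n = 2) in tumor-dissociated vector cells and 160.7 ± 1.36 (n = 2) in tumor-dissociated JMJD3 cells, and it was above the background level on 1 of 8 arrays. Without the filter on dim probes, limma gave KDM6B a log2 change of 0.17 with JMJD3 in cultured cells (adjusted p = 1.00) and of 0.47 in tumor-dissociated cells (adjusted p = 0.382). Whether the introduced JMJD3 sequence contains the probed part is not given in the sources used here, so this probe may check nothing about the labels.

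In cultured cells, JMJD3 was accompanied by higher expression of a small set of genes. The inflammatory chemokine CXCL8 rose by 2.58 ± 0.21 on the log2 scale (SE, 2 arrays per group, limma adjusted p = 0.00254), a fold change of 5.96. STC1, which encodes the secreted glycoprotein stanniocalcin 1, rose 8.84-fold (log2 change 3.14 ± 0.33, limma adjusted p = 0.0114). TNFRSF11B, the decoy receptor osteoprotegerin, rose 6.08-fold, and the small proline-rich protein gene SPRR2D rose 10.6-fold. FGFBP1, which encodes a carrier of fibroblast growth factors, was not above background in vector cells and was at least 6.47-fold higher with JMJD3 (limma adjusted p = 0.00183).

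In total 11 of 12415 genes were called, 11 higher and 0 lower, while 539 genes had an unadjusted p under 0.05 in limma where chance gives 621. These p-values use a spread pooled over all 4 groups, which was wider in tumor-dissociated cells than in culture. A fit of only the cultured arrays called 44 genes, the 11 among them. The low counts therefore do not show that culture held fewer effects than tumor-dissociated cells. The bounded increases were at least 8.21-fold for the matrix metalloproteinase MMP10, at least 5.75-fold for RGS4, a regulator of G protein signalling, and at least 3.66-fold for SPRR2F. The other 3 of the 11 called genes, named after their values were seen, were the urea transporter SLC14A1 (log2 change 2.14), VAT1L (1.93) and TFPI, an inhibitor of coagulation (1.24). The chemokine gene CCL2 had a log2 difference of 2.18 ± 0.56 and did not pass (limma adjusted p = 0.511), although its mean intensity was 292 ± 16.7 (SD, n = 2) in vector and 958 ± 44.0 (n = 2) in JMJD3 cells. Its pooled standard error includes the tumor-dissociated JMJD3 arrays, on which CCL2 measured 7370 and 1581. BMP4 was above background on 0 of 8 arrays.

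Among the lists, 1 of 20 NF-kB targets rose, CXCL8, and 3 rose when adjusted over the list alone. PTGS2, the inducible cyclooxygenase, had a log2 difference of 1.75 ± 0.35 that did not pass over all genes. The list's mean was 0.42 (camera adjusted p = 0.00142, and adjusted p = 0.433 with an estimated correlation). Of 16 secreted angiogenic and growth factors, 1 rose over all genes, STC1, and 4 when adjusted over the list alone, with a mean of 0.44 (camera adjusted p = 7.57e-05, and adjusted p = 0.311 with an estimated correlation). PDGFC differed by 1.09 ± 0.20 without passing. No member of the 34 matrix and protease genes passed over all genes and 3 rose when adjusted over the list alone; the interstitial collagenase MMP1 had a log2 difference of 3.56 ± 0.53 (limma adjusted p = 0.0731), and the list mean was 0.31 (camera adjusted p = 0.00578, and adjusted p = 0.311 with an estimated correlation). Neither did any of 29 interferon-stimulated genes pass, with a mean of 0.21 (camera adjusted p = 0.00142, and adjusted p = 0.527 with an estimated correlation). The 19 genes of the invasive melanoma state averaged 0.26, led by EGFR at 0.74 ± 0.22, with 0 called (camera adjusted p = 0.00179, and adjusted p = 0.433 with an estimated correlation). Unfolded protein response genes averaged -0.21 over 20 members with 0 called, led by ASNS at -0.70 ± 0.31 (camera adjusted p = 0.00142, and adjusted p = 0.433 with an estimated correlation). The 10 fibroblast markers averaged 0.23 with 0 called (camera adjusted p = 0.0367, and adjusted p = 0.433 with an estimated correlation). Without cultured vector replicate 1 and replicate 2 in turn, the interferon mean was 0.38 and 0.034 and the unfolded protein mean -0.12 and -0.30. Without cultured JMJD3 replicate 1 and replicate 2 the invasive state mean was 0.39 and 0.13. Lists of Polycomb and H3K27 enzymes (16 genes, mean -0.07, camera adjusted p = 0.423) and HOX genes (23 genes, mean 0.02, camera adjusted p = 0.770) held 0 called members each.

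Every one of the 8 genes with the largest rises lost its call in at least 1 of the 8 fits that left out an array, while their log2 changes stayed between 2.22 and 3.63. The count of called genes was 2 without cultured vector replicate 1, 2 without cultured vector replicate 2, 2 without cultured JMJD3 replicate 1, 0 without cultured JMJD3 replicate 2, and 36 without either replicate 1 or replicate 2 of the tumor-dissociated JMJD3 cells.

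**Figure D1:**
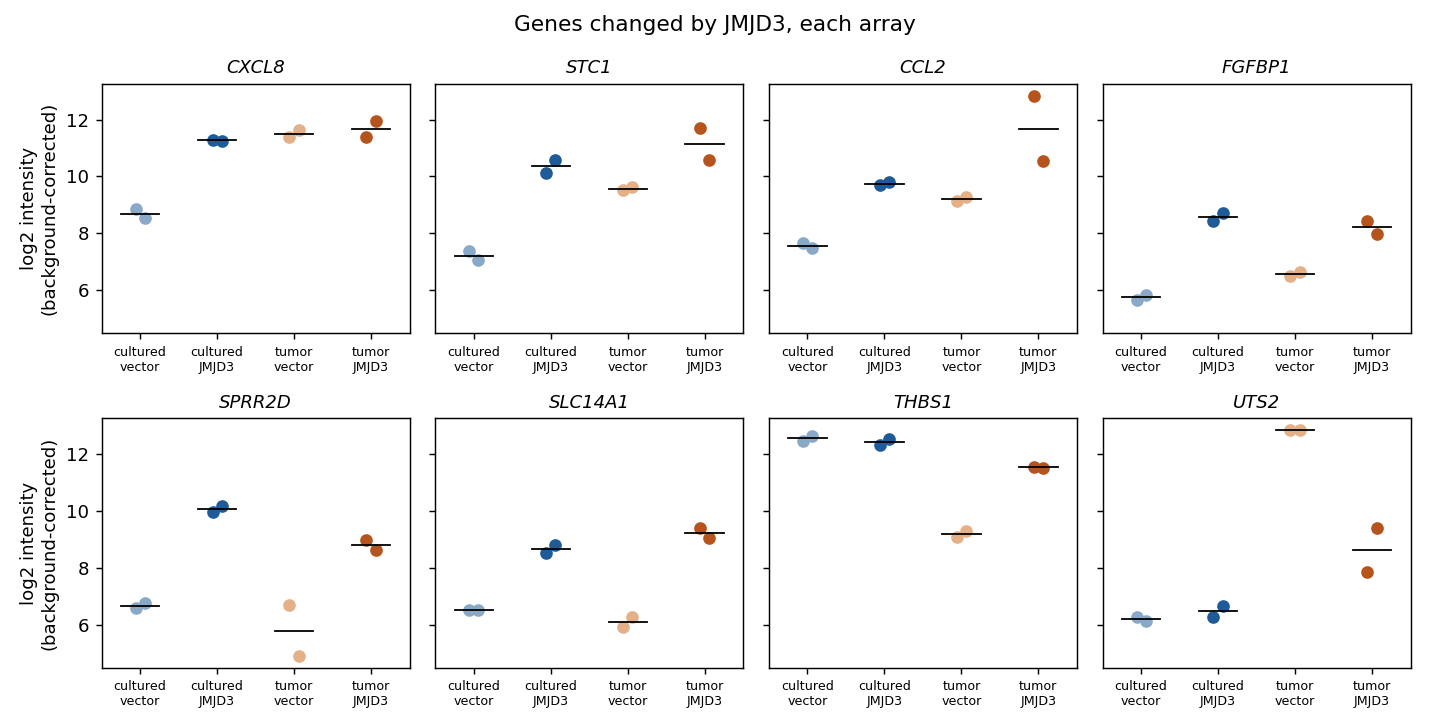
Each point is 1 array, with log2 background-corrected intensity on the vertical axis and the 4 groups on the horizontal axis; the line is the mean of 2 arrays. SPRR2D and SLC14A1 were called higher with JMJD3 in both origins, whereas CXCL8 was called in cultured cells, and THBS1 and UTS2 in tumor-dissociated cells.

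In cells dissociated from tumors, JMJD3 was accompanied by changes in both directions. The largest rises were in DMBT1, a secreted scavenger receptor protein, which was at least 15.6-fold higher, and in the LIM domain-binding gene LDB2, which rose 11.1-fold (log2 change 3.47 ± 0.55, 2 arrays per group, limma adjusted p = 0.0246). SLC14A1 rose 8.78-fold and SPRR2D 8.16-fold, and THBS1, the matrix glycoprotein thrombospondin 1, rose 5.08-fold (log2 change 2.34 ± 0.16, limma adjusted p = 0.000445). UTS2, which encodes the vasoactive peptide urotensin 2, fell by 4.22 ± 0.40 on the log2 scale (limma adjusted p = 0.00394), and the membrane metalloendopeptidase MME fell by 2.94. The cell surface protein TSPAN8 was at least 5.99-fold lower with JMJD3, and the cadherin CDH6 at least 4.77-fold lower. Without tumor-dissociated JMJD3 replicate 1 and replicate 2 in turn, LDB2 stood at 2.66 and 4.29 on the log2 scale. In the same 2 fits UTS2 stood at -3.45 and -5.00 and MME at -2.20 and -3.69. The log2 change of DMBT1 differed by more than 1.5 times between these 2 fits. SPRR2D stood at 3.93 without tumor-dissociated vector replicate 1 and 2.13 without replicate 2.

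Of 12415 genes 102 were called, 46 higher and 56 lower. Other large rises were in the fatty acid-binding protein FABP4 (at least 4.32-fold), the cytoskeletal adaptor SORBS2 (log2 change 2.35) and the Notch-responsive repressor HEY2 (2.26). The remaining large falls were in PASD1 (at least 5.69-fold), the long noncoding RNA LINC01139 (at least 4.55-fold), TMEFF2 (log2 change -2.68) and the retinoic acid-binding protein CRABP2 (-2.63). SPRR2D was above background on 1 of the 2 vector arrays, and TMEFF2 on 1 of the 2 JMJD3 arrays. Without tumor-dissociated vector replicate 1 and replicate 2 in turn TMEFF2 stood at -3.33 and -2.03 and HEY2 at 2.84 and 1.68. The log2 change of PASD1 differed by more than 1.5 times between these 2 fits. CRABP2 stood at -2.10 and -3.16 without tumor-dissociated JMJD3 replicate 1 and replicate 2. CXCL8, at 3031 ± 324 (SD, n = 2) in vector and 3422 ± 899 (n = 2) in JMJD3 cells, did not differ detectably (log2 difference 0.16 ± 0.21, limma adjusted p = 0.822). STC1 differed by 1.58 ± 0.33 (limma adjusted p = 0.0744) and CCL2 by 2.47 ± 0.56 (limma adjusted p = 0.0895), and neither passed. CCL2 measured 7370 on replicate 1 and 1581 on replicate 2 of the tumor-dissociated JMJD3 cells.

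Of 18 BMP and SMAD genes 1 rose, the ligand gene BMP2 (log2 change 1.75 ± 0.27), and 2 when adjusted over the list alone, with a mean of 0.31 (camera adjusted p = 0.0128, and adjusted p = 0.357 with an estimated correlation). PTGS2 rose by 2.25 ± 0.35 as the 1 called member of the 20 NF-kB targets, 4 of which rose and 1 fell when adjusted over the list alone. The mean over the list was 0.42 (camera adjusted p = 0.00735, and adjusted p = 0.417 with an estimated correlation). THBS1 and IGFBP3 (1.02 ± 0.16) were the 2 called of 16 secreted angiogenic and growth factors, with 4 rising when adjusted over the list alone. Together these genes averaged 0.37 (camera adjusted p = 0.0291, and adjusted p = 0.417 with an estimated correlation). Among 23 hypoxia and glycolysis genes the collagen prolyl hydroxylase P4HA2 rose by 1.18 ± 0.21, and 3 rose when adjusted over the list alone. The list's mean log2 change was 0.30 (camera adjusted p = 0.00239, and adjusted p = 0.357 with an estimated correlation). The 19 genes of the invasive state had 0 called over all genes and 6 higher when adjusted over the list alone, with TNC at 1.29 ± 0.26. Averaged over the list, the change was 0.39 (camera adjusted p = 0.00239, and adjusted p = 0.417 with an estimated correlation). The 34 matrix genes averaged 0.28 (camera adjusted p = 0.00337, and adjusted p = 0.357 with an estimated correlation), but their 1 called member, the fibrillar collagen gene COL3A1, fell by 1.44 ± 0.21; when adjusted over the list alone 6 rose and 4 fell. The epithelial keratin KRT8 fell by 1.73 ± 0.23, the 1 called of 14 epithelial-mesenchymal genes (mean -0.00091, median 0.076, camera adjusted p = 0.880). MAPK output genes averaged 0.26 over 20 members with 0 called (camera adjusted p = 0.0199, and adjusted p = 0.442 with an estimated correlation), and 6 keratinocyte and erythroid markers averaged 0.35 with 0 called (camera adjusted p = 0.0291, and adjusted p = 0.357 with an estimated correlation).

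Means moved by more than 1.5 times for 4 of the lists above. Without tumor-dissociated JMJD3 replicate 1 and replicate 2 in turn they were 0.25 and 0.59 for NF-kB targets and 0.15 and 0.40 for matrix genes. Without tumor-dissociated vector replicate 1 and replicate 2 they were 0.43 and 0.19 for BMP genes and 0.51 and 0.18 for keratinocyte and erythroid markers. Other lists moved less. Hypoxia genes averaged 0.20 and 0.40 without tumor-dissociated JMJD3 replicate 1 and replicate 2, and MAPK output genes 0.32 and 0.20. The invasive state mean was 0.28 and 0.49 without tumor-dissociated vector replicate 1 and replicate 2.

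Antigen presentation genes were higher on average with JMJD3, by 0.59 over 20 genes with 0 called (camera adjusted p = 0.000491, and adjusted p = 0.449 with an estimated correlation), and cell cycle genes were lower, by -0.27 over 31 genes with 1 called, the centromere protein CENPE at -1.51 ± 0.23 (camera adjusted p = 0.00148, and adjusted p = 0.604 with an estimated correlation). Each of these shifts rested on 1 array. Without tumor-dissociated vector replicate 2 the antigen presentation mean was 0.046, and 1.13 without replicate 1; HLA-DRA stood at 8.52 on replicate 2 on the log2 scale against 11.75 to 12.41 on the other 3 tumor-dissociated arrays. Without tumor-dissociated JMJD3 replicate 1 the cell cycle mean was 0.0033, and -0.55 without replicate 2.

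The number of called genes was 16 without tumor-dissociated vector replicate 2 and 177 without replicate 1, 44 without tumor-dissociated JMJD3 replicate 1 and 426 without replicate 2, 63 without either cultured vector array, and 59 without either cultured JMJD3 array. A fit of only the tumor-dissociated arrays called 15 genes, and the fit without both arrays that stood apart on the second component called 25, of which 18 were among the 102.

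Genes that rose with JMJD3 in both origins included FGFBP1, SLC14A1, SPRR2D, SPRR2F and VAT1L. These 5 of the 11 and 46 higher genes compare with 0.0408 for independent lists; the 2 contrasts share no array but do share the pooled spread of each gene. With only the compared groups in each fit, 1 gene, SLC14A1, was shared by the 43 and 8 higher genes, against 0.0277 (one-sided Fisher's exact test, p = 0.0274), and above background on all 8 arrays 1 gene was shared. Of the 11 genes higher in culture, 9 had a positive difference in tumor-dissociated cells, and of the 46 higher there, 39 had one in culture. Across all 12415 genes, which are not independent replicates, the log2 changes of the 2 contrasts correlated with Pearson's r = 0.23. The shared count was 1 without cultured vector replicate 1, 2 without cultured vector replicate 2, 2 without cultured JMJD3 replicate 1, 0 without cultured JMJD3 replicate 2, 2 without tumor-dissociated vector replicate 2 and 25 without tumor-dissociated JMJD3 replicate 2.

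The JMJD3 effect differed between origins in 13 genes by the test of the difference itself. THBS1 rose with JMJD3 by 2.34 in tumor-dissociated cells against a difference of -0.11 in culture (log2 difference of effects 2.46 ± 0.23, limma adjusted p = 0.0118), and OLFML2A and the transcriptional regulator ZBTB38 were the other 2 genes with a more positive effect in tumor-dissociated cells. CXCL8 went the other way, with 2.58 in culture and 0.16 in tumor-dissociated cells (difference -2.42 ± 0.30, limma adjusted p = 0.0321). UTS2 (difference -4.49 ± 0.57, limma adjusted p = 0.0323), SPP1, which encodes osteopontin (-3.27), VAV3 (-2.28), PBX3 (-1.78), the calcineurin regulator RCAN2, LINC01139, CDH6, TSPAN8 and MFAP4 had a more negative effect in tumor-dissociated cells. RCAN2, LINC01139, CDH6, TSPAN8 and MFAP4 were not above background on either array of both cultured groups, so the sizes of their differences rest on the floor and are not given here. PBX3 and MFAP4 were named after their values were seen. UTS2 stood at -3.72 without tumor-dissociated JMJD3 replicate 1 and -5.27 without replicate 2. The count was 0 without cultured vector replicate 1, cultured vector replicate 2 or cultured JMJD3 replicate 1, 3 without cultured JMJD3 replicate 2, 2 without tumor-dissociated vector replicate 2, 65 without tumor-dissociated vector replicate 1 and 69 without tumor-dissociated JMJD3 replicate 2.

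**Figure D2:**
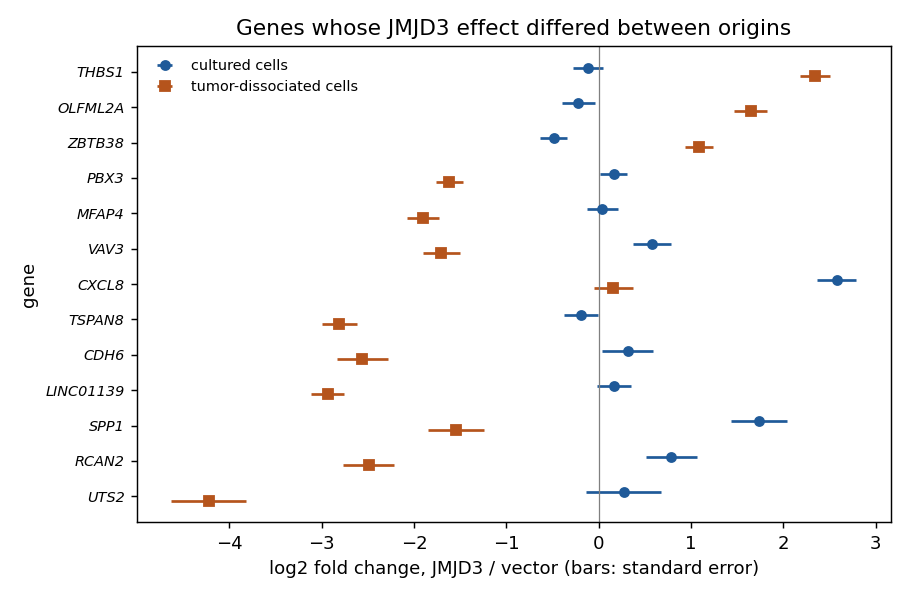
The horizontal axis gives the log2 fold change of JMJD3 over vector, with standard errors as bars, for the 13 genes whose effect differed between origins; circles are cultured cells and squares tumor-dissociated cells. THBS1, OLFML2A and ZBTB38 lie further right in tumor-dissociated cells, and the other 10 genes further left. For RCAN2, LINC01139, CDH6, TSPAN8 and MFAP4 the positions rest on values below background in cultured cells.

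Vector cells taken from tumors differed widely from the cultured vector cells. UTS2 rose 102-fold (log2 change 6.67 ± 0.40, 2 arrays per group, limma adjusted p = 2.89e-05). RCAN2 was at least 30.5-fold higher, the adhesion molecule VCAM1 at least 26.7-fold, MME at least 18.8-fold and the endothelin gene EDN3 at least 17.9-fold. SPP1 rose 36.7-fold, QPRT, an enzyme of NAD synthesis, 33.0-fold, and RAC2 30.5-fold. The calcium-activated chloride channel ANO1 fell by 3.61 on the log2 scale, and the log2 change of THBS1 was -3.36 ± 0.16 (limma adjusted p = 9.08e-06).

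Of 12415 genes 1258 were called, 763 higher and 495 lower. The other large falls were in the epidermal protein gene FLG (at least 4.71-fold), the glutamate receptor gene GRM8 (at least 3.96-fold), CD96 (log2 change -2.90), TESC (-2.75), the HLA class II invariant chain CD74 (-2.81) and HLA-DRB4 (-2.74). ANO1 and TESC were each above background on 1 of the 2 tumor-dissociated arrays, and stood at -4.41 and -3.46 without tumor-dissociated vector replicate 1 and at -2.81 and -2.04 without replicate 2. CD74 lost its call in 6 and HLA-DRB4 in 5 of the 8 fits that left out an array. They differed by -1.21 and -1.35 without tumor-dissociated vector replicate 2 and by -4.41 and -4.14 without replicate 1. HLA-DRB4 probes can bind transcripts of related HLA-DRB genes, and 1 of its other probes had a difference of 0.20.

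Of 29 interferon-stimulated genes 16 rose in vector cells, 0 fell and 13 did not pass, and 28 had a positive difference. IFITM1 rose by 4.53 ± 0.33, the transcription factor IRF9 by 1.71 ± 0.21 and the antiviral GTPase MX1 by 1.15 ± 0.18, and BST2, which encodes tetherin, rose from below background (limma adjusted p = 0.00298). The list's mean was 1.03 (camera adjusted p = 1.22e-10, and adjusted p = 0.188 with an estimated correlation), and 17 rose and 1 fell when adjusted over the list alone. Of 10 fibroblast markers 7 rose and 10 were positive, with COL3A1 at least 5.41-fold higher, POSTN, which encodes periostin, at least 2.44-fold, COL1A2 up by 2.38 ± 0.25 and the growth factor receptor PDGFRA by 2.75 ± 0.40. The mean over the list was 1.82, with 8 rising when adjusted over the list alone (camera adjusted p = 9.22e-09, and adjusted p = 0.0696 with an estimated correlation). The fibroblast markers DCN (0.55 ± 0.32) and LUM (0.57 ± 0.27) did not pass. Of 34 matrix and protease genes, 4 of them also fibroblast markers, 11 rose and 4 fell; the cysteine protease CTSK rose by 2.90 ± 0.17 and COL6A3 by 3.04 ± 0.19, while TNC fell by 1.80. Together these genes averaged 0.67, with 12 rising and 4 falling when adjusted over the list alone (camera adjusted p = 0.00784, and adjusted p = 0.161 with an estimated correlation).

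Of 15 cholesterol synthesis genes 4 rose, MVK (0.90), LSS (0.80), DHCR7 (1.21) and MSMO1 (0.80), and 10 when adjusted over the list alone. The list's mean log2 change was 0.56 (camera adjusted p = 5.30e-05, and adjusted p = 0.161 with an estimated correlation). Among 20 NF-kB targets 5 rose and 3 fell; VCAM1, CXCL8 (2.82 ± 0.21) and the inhibitor TNFAIP3 (2.35 ± 0.20) rose, and 8 rose and 4 fell when adjusted over the list alone. Averaged over the list, the change was 0.70 (camera adjusted p = 0.0445, and adjusted p = 0.626 with an estimated correlation). The epithelial-mesenchymal list had 3 of 14 rising, the mesenchymal cadherin CDH11 (at least 8.02-fold) with the epithelial keratins KRT8 (3.90 ± 0.23) and KRT18 (1.24 ± 0.19), and 5 rising and 1 falling when adjusted over the list alone. The mean over the list was 0.67 (camera adjusted p = 0.00784, and adjusted p = 0.161 with an estimated correlation). The invasive state list had 2 of 19 rising and 3 falling, with the transcription factor SOX9 at least 16.2-fold higher and FOSL1 at -1.09 (mean 0.10, median -0.022, camera adjusted p = 0.930). Of 18 heat shock and immediate early genes 4 fell and 1 rose, with FOSB at -2.08 and KLF4 at -1.52. Together these genes averaged -0.40 (camera adjusted p = 0.0413, and adjusted p = 0.188 with an estimated correlation). Keratinocyte and erythroid markers had 2 of 6 lower, KRT14 at least 2.07-fold and HBA2 at least 1.83-fold. The list's mean log2 change was -0.70 (camera adjusted p = 0.0242, and adjusted p = 0.188 with an estimated correlation). Among 20 antigen presentation genes 4 fell, with the class II transactivator CIITA at -1.95 and HLA-B at -1.49 (mean -0.79, camera adjusted p = 0.0445, and adjusted p = 0.727 with an estimated correlation), and the mean was -0.25 without tumor-dissociated vector replicate 2 and -1.33 without replicate 1. Cell cycle genes averaged -0.27 over 31 members with 0 called (camera adjusted p = 0.0259, and adjusted p = 0.748 with an estimated correlation), at -0.16 without tumor-dissociated vector replicate 1 and -0.37 without replicate 2.

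The tests of several other lists did not pass in vector cells. Of 10 melanocyte differentiation genes 1 fell, LEF1 at -2.62 ± 0.38, and 2 rose and 3 fell when adjusted over the list alone (mean -0.57, median -0.23, camera adjusted p = 0.521). The leukocyte list had CORO1A higher and LYZ lower of 9 (mean -0.053, median 0.21, test upward, camera adjusted p = 0.813), with another LYZ probe at 0.03, and the 2 endothelial markers measured had 0 called (camera adjusted p = 0.549). Of 19 p53 targets 1 rose, TP53INP1 at 0.84 (camera adjusted p = 0.924), and of 28 ribosomal protein genes 0 were called (mean 0.027, median -0.0030, camera adjusted p = 0.776). The count of called genes in vector cells was 521 without cultured vector replicate 1, 348 without cultured vector replicate 2 and 549 without tumor-dissociated vector replicate 2, and between 926 and 1581 without each of the other 5 arrays.

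**Figure D3:**
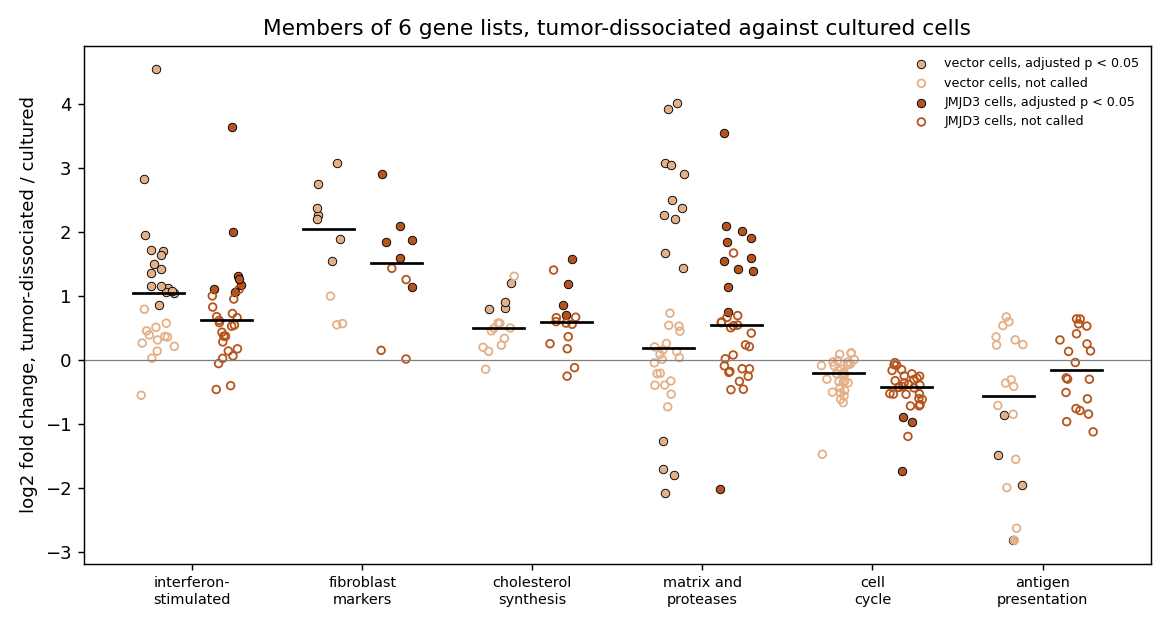
Each point is a gene of 1 of 6 lists, with the log2 fold change of tumor-dissociated over cultured cells on the vertical axis for vector cells (light) and JMJD3 cells (dark); filled points had an adjusted p under 0.05 and the line is the list's median. Of 29 interferon-stimulated genes 16 rose in vector and 7 in JMJD3 cells, and of 10 fibroblast markers 7 and 6.

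JMJD3 cells taken from tumors also differed widely from their cultured counterparts. VCAM1 was at least 15.5-fold higher, the calcium channel subunit CACNA2D4 at least 9.15-fold and PAMR1 at least 4.84-fold. QPRT rose 15.8-fold (log2 change 3.98 ± 0.18, 2 arrays per group, limma adjusted p = 3.29e-05), RAC2 13.0-fold, IFITM1 12.4-fold, COL6A3 11.7-fold and SOX9 9.35-fold. FLG was at least 3.76-fold lower, the gelatinase MMP9 at least 2.18-fold lower and TH, the tyrosine hydroxylase of catecholamine synthesis, at least 2.11-fold lower. ANO1 fell by 2.37 ± 0.51 on the log2 scale (limma adjusted p = 0.0336), at -1.71 without tumor-dissociated JMJD3 replicate 1 and -3.03 without replicate 2. The log2 changes of the cytokine IL24, the phosphatase inhibitor CIP2A, the ephrin receptor EPHB1 and CENPE were -1.96, -1.80, -1.74 and -1.74. Without tumor-dissociated JMJD3 replicate 1 these were -1.50, -1.41, -1.32 and -1.38, and without replicate 2 -2.42, -2.18, -2.16 and -2.10.

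Of 12415 genes 740 were called, 467 higher and 273 lower. Fibroblast markers were again among those that rose, 6 of 10, with POSTN up by 1.84 ± 0.23, the receptor PDGFRB by 2.90 ± 0.43, smooth muscle actin ACTA2 by 1.87 ± 0.28 and COL1A2 by 1.58 ± 0.25. Averaged over the list, the change was 1.43, with 8 rising when adjusted over the list alone (camera adjusted p = 1.00e-06, and adjusted p = 0.0923 with an estimated correlation). DCN (0.01 ± 0.32) and LUM (0.15 ± 0.27) did not pass. Of 2 endothelial markers 1 rose, PECAM1 at least 1.27-fold (camera adjusted p = 0.440), and of 9 leukocyte markers 1 fell, LYZ at -1.58 with another of its probes at 0.16 (camera adjusted p = 0.701). Of 34 matrix genes 11 rose and 1 fell, with CTSK at 2.01 and MMP9 as the 1 that fell. The mean over the list was 0.64, with 13 rising and 1 falling when adjusted over the list alone (camera adjusted p = 2.32e-05, and adjusted p = 0.0923 with an estimated correlation). Interferon-stimulated genes had 7 of 29 rising, among them MX1 (1.31 ± 0.18), IRF9 (1.05) and BST2 (1.99), and 11 when adjusted over the list alone. Together these genes averaged 0.71 (camera adjusted p = 1.00e-06, and adjusted p = 0.280 with an estimated correlation). The same 4 cholesterol synthesis genes rose, MSMO1 (1.18, with another of its probes at -0.039), DHCR7 (1.57), MVK (0.85) and LSS (0.70), and 10 of 15 when adjusted over the list alone. The list's mean log2 change was 0.61 (camera adjusted p = 5.70e-06, and adjusted p = 0.0931 with an estimated correlation).

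NF-kB targets had 4 of 20 rising, VCAM1, TNFAIP3 (1.60), TNFAIP2 (1.12) and the cytokine IL6 (at least 2.29-fold), and 6 rising and 1 falling when adjusted over the list alone. Averaged over the list, the change was 0.70 (camera adjusted p = 0.000713, and adjusted p = 0.280 with an estimated correlation). Of 14 epithelial-mesenchymal genes 2 rose, CDH11 (2.47) and KRT8 (2.25), and 4 when adjusted over the list alone. The mean over the list was 0.60 (camera adjusted p = 0.00246, and adjusted p = 0.133 with an estimated correlation). Cell cycle genes had 3 of 31 falling, CENPE, CENPF (-0.97) and the kinase CDK1 (-0.89), and 0 positive. Together these genes averaged -0.49 (camera adjusted p = 1.65e-06, and adjusted p = 0.504 with an estimated correlation), at -0.22 without tumor-dissociated JMJD3 replicate 1 and -0.77 without replicate 2. The count of called genes was 384 without either cultured vector array, 127 without cultured JMJD3 replicate 1, 39 without cultured JMJD3 replicate 2, 182 without tumor-dissociated JMJD3 replicate 1 and 1307 without tumor-dissociated JMJD3 replicate 2. A fit of only the JMJD3 arrays called 263 genes, the fit without the filter on dim probes 418, and the fit without both arrays that stood apart 368.

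The difference between tumor-dissociated and cultured cells was partly shared between vector and JMJD3 cells. Dissociation and passages belong to both contrasts, so they cannot be told apart here from growth in a tumor. Of the 763 and 467 higher genes 339 were the same, against 28.7 for independent lists, and of the 495 and 273 lower genes 90 were the same, against 10.9; 1 gene was called in opposite directions. With only the compared groups in each fit, 180 of 831 and 204 higher genes were the same, against 13.7 (one-sided Fisher's exact test, p = 3.49e-190), and 27 of 485 and 59 lower genes, against 2.30 (p = 7.09e-23). Genes are not independent replicates, so these p-values are too small. The log2 changes of the 2 contrasts correlated across 12415 genes with Pearson's r = 0.72, with a slope of 0.59 for JMJD3 on vector cells. Among the shared genes were VCAM1, QPRT, RAC2, IFITM1, COL6A3, SOX9 and CDH11 as higher and ANO1, FLG and THBS1 as lower.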

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

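The test of the difference between origins was set before the data were examined, and the tests of saturation, of the group lying farthest, of fibroblast and host-animal cells and of shared arrays were chosen after the results had been seen. The JMJD3 effect differed between cultured and tumor-dissociated cells, by the test of the difference, in 13 genes. It also differed in 6 gene lists at camera's preset correlation, and in 0 of them with an estimated one (adjusted p = 0.556 to 0.751). The log2 effect in tumor-dissociated minus that in cultured cells was 2.46 for THBS1, 1.87 for OLFML2A and 1.57 for ZBTB38. It was -2.42 for CXCL8, -1.78 for PBX3, -3.27 for SPP1, -4.49 for UTS2, -2.28 for VAV3, -3.28 for RCAN2, -1.94 for MFAP4, -2.62 for TSPAN8, -2.87 for CDH6 and -3.10 for LINC01139. For RCAN2, MFAP4, TSPAN8, CDH6 and LINC01139, 5 of the 13, the sizes rest on values below background in both cultured groups.

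The mean log2 difference was -0.32 for interferon-stimulated genes, 0.64 for antigen presentation, -0.23 for cell cycle, 0.31 for hypoxia and glycolysis, 0.26 for the unfolded protein response and 0.39 for MAPK output, each at camera's preset correlation. With an estimated correlation their adjusted p-values were 0.710, 0.710, 0.751, 0.556, 0.566 and 0.556. Without replicate 1 and replicate 2 of the named group in turn, the antigen presentation difference was 1.19 and 0.10 (tumor-dissociated vector), cell cycle 0.050 and -0.50 and the unfolded protein response 0.39 and 0.13 (tumor-dissociated JMJD3), interferon -0.49 and -0.15 (cultured vector), and MAPK output 0.54 and 0.25 (cultured JMJD3).

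Saturated probes in tumor-dissociated cells were argued against for these 13 genes, since their highest intensity there was 27.8% of the highest on the arrays. The tumor-dissociated vector group lay farthest from the other 3 groups in 11 of the 13 genes, and the cultured vector group in the other 2, SPP1 and CXCL8. For 3 of the 11, below background in all other groups, no other outcome was possible, and among the 8 genes above background on at least 1 array of each group the count was 6. UTS2, RCAN2 and VAV3 were called higher than in culture, and THBS1 lower, in tumor-dissociated cells of both kinds, so these genes differed in degree. A candidate explanation is a difference that was stronger in the tumor-dissociated vector cells, in which UTS2, RCAN2 and VAV3 were high and THBS1 and ZBTB38 low. Whether this lies in those 2 preparations or in vector cells grown as tumors stays open, because the labels give no tumor of origin, as does a biological effect of JMJD3 on how cells change in tumors, which was not tested.

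Of 10 fibroblast markers 6 rose in tumor-dissociated cells of both kinds, while the list's own call was lost in both with an estimated correlation (adjusted p = 0.0696 and 0.0923). DCN and LUM, abundant in fibroblasts, fell short of the median of the other 8 markers by at least 5.28 of their own standard errors. These genes were picked after they had been seen not to pass, and the spread of the other markers was not counted. The shortfall therefore cannot decide whether fibroblasts with human transcripts were carried over from the tumor. The largest difference over all 6 DCN and LUM probes was 0.74 in vector and 0.61 in JMJD3 cells. Cells of a host animal could also contribute if their transcripts bound the human probes unevenly. That cannot be told apart from a change in the melanoma cells, because no probe or host sequence was used here. Of the 10 markers, 5 were above background on both cultured vector arrays and 4 on both cultured JMJD3 arrays, and 4 are also on the matrix list.

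Genes raised by JMJD3 in culture were often also higher in tumor-dissociated vector cells, 8 of 11 (CXCL8, FGFBP1, MMP10, RGS4, STC1, TFPI, TNFRSF11B and VAT1L), against 0.676 for independent lists. Both comparisons use the cultured vector arrays, and chance lows on those arrays may contribute. In 100 simulations with no effect at all the highest count was 7 and the mean 2.69. With unchanged tumor-dissociated vector cells the highest was 2. That setting kept the 11 genes fixed, so choosing genes on chance lows could not act in it, and it cannot decide the question. Controls were then split so that no array was shared. The 11 genes with the largest JMJD3 effect against cultured vector replicate 1 had 7 higher against replicate 2 (median log2 difference 1.34). Those chosen against replicate 2 had 9 higher against replicate 1 (median 1.15). These counts lie between the 10 of 11 that would have argued against shared arrays as the whole cause and the 6 that would have fitted them. Shared arrays therefore cannot be told apart here from a program common to JMJD3 and the tumor-dissociated state.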

How the results depend on the processing

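The relaxed background level, the level from 1 array, the offset of 50, the level on all 8 arrays, the fit without 2 arrays and the estimated correlation were chosen after seeing the data. Counts are given in the order cultured JMJD3, tumor-dissociated JMJD3, tumor state in vector cells, tumor state in JMJD3 cells, difference of effects, and shared JMJD3 genes, with 11, 102, 1258, 740, 13 and 5 as reported. Counts stayed within 1.5 times of these with cyclic loess, the relaxed level, the level from 1 array (12154 genes tested), the offset of 50, and all probes. The fit of all probes counts probes instead of genes, with 22287 tested. Its calls included 10 of the 11, 100 of the 102, 1146 of the 1258, 631 of the 740 and 13 of the 13 genes. The cause of the following moves was not tested unless stated. With log2 of the value plus 16 and no background correction, the first 2 counts were 5 and 57 and the shared count 3, and with the deposited values as they are the first 2 were 5 and 65. Without a filter the tumor state in JMJD3 cells gave 418, where 20046 genes were tested. Above background on all 8 arrays, with 10004 genes tested, the counts were 5, 55, 7 for the difference and 1 shared. With only the compared groups fitted they were 44, 15, 263 for the tumor state in JMJD3 cells and 1 shared. Array weights gave 42, 57 and 10 shared. A 2-fold minimum left 662 and 373 for the tumor state, and an adjusted p under 0.01 left 4, 23, 460, 81, 1 and 3, both by construction. Without both arrays that stood apart, counts were 44, 25, 368 for the tumor state in JMJD3 cells and 3 shared.

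Leaving out 1 array at a time, with a lone array assumed to vary like the other groups, gave 0 to 36, 16 to 426, 348 to 1581, 39 to 1307, 0 to 69 and 0 to 25. Over these fits named genes lost their call 131 times, gained one 5 times and kept it or stayed uncalled 431 times, and 1 changed sign, CXCL8 in tumor-dissociated cells, at -0.12 without tumor-dissociated JMJD3 replicate 2 and 0.44 without replicate 1.

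The replicate numbers do not pair the arrays by the labels, and deviations of same-numbered arrays correlated at 0.046 to 0.371 over the 6 pairs of groups. With the replicate number as a block, the counts that moved were 168 for tumor-dissociated JMJD3, 1161 for the tumor state in JMJD3 cells and 35 for the difference. Blocked within origin or JMJD3 status they were 6, 197 and 1 for the difference.

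The signs of 7 list means turned, in 3 fits. Keratinocyte and erythroid markers in vector cells averaged 0.069 above background on all 8 arrays. For JMJD3 in tumor-dissociated cells, cell cycle genes averaged 0.0033 without tumor-dissociated JMJD3 replicate 1, -0.55 without replicate 2 and 0.11 without both arrays that stood apart, and antigen presentation -0.064 without both. For the difference of effects, cell cycle averaged 0.050, -0.50 and 0.16 in the same fits, and antigen presentation -0.010. All 40 list calls were lost with an estimated correlation. Slide blocks, median scaling and detection p filters were not run. Signal over background limits genes such as KDM6B, BMP4 and those given as bounds.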

Other observations

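Small nucleolar RNAs guide the modification of ribosomal and spliceosomal RNA. Probes named for their genes were called lower in tumor-dissociated cells more often than those of other genes, though most did not pass. Whether these probes measured the mature small nucleolar RNAs was not tested. This family and the collagens were found after seeing the data, in a scan of 159 families defined by the first letters of gene symbols, with the 2 classes of small nucleolar RNA joined after they had been seen apart. Of 139 measured, 19 fell and 0 rose in vector cells, with a median log2 change of -0.40 (one-sided Fisher's exact test against the other genes, adjusted p = 0.000811), and 26 fell and 0 rose in JMJD3 cells, with a median of -0.44 (adjusted p = 8.96e-15). The sign was negative in 84.9% and 89.9% of members. SNORD14A fell by 0.98 in vector and 0.70 in JMJD3 cells, SNORD17 by 1.26 and 1.11, and the log2 changes of SNORD99 were -0.69 and -1.10. With cyclic loess 14 and 17 fell, with medians of -0.35 and -0.40; with the deposited values as they are 13 and 14 fell, with medians of -0.22 and -0.23; and with 16 added to these 13 and 13 fell. None rose in these fits. Genes of a family can share RNA quality and labelling, so members are not independent and the p-values are too small.

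Collagen genes were called higher more often than other genes, 9 of 29 in vector cells (adjusted p = 0.00622) and 7 of 29 in JMJD3 cells (adjusted p = 0.0123), but not as 1 family: 5 fell in vector and 1 in JMJD3 cells. In vector cells COL8A1 rose by 4.01 and COL1A1 by 2.26, while the basement membrane collagens COL4A1 and COL4A2 fell by 1.71 and 1.27. With cyclic loess 9 rose and 5 fell in vector cells, and 7 rose and 0 fell in JMJD3 cells.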
